A study of Caenorhabditis elegans with 2 samples.

How the data were processed

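Total RNA from 2 samples of a C. elegans strain carrying daf-2(e1370) and daf-12(m20) was converted to TruSeq libraries and sequenced, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, the Illumina base calling and demultiplexing software. The aligner, the counting method, the annotation and the genome build are not given in the sources used here. The authors deposited 1 table with an RPKM value for each gene and replicate, per the file headers. RPKM divides reads by gene length and by the reads of the library, so it keeps no totals and a large change in a few abundant genes shifts all others. Because the values are RPKM and not counts, no count model was used.

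The table held 19990 rows. Values of 1000 or more carried a comma as digit separator (205 in replicate 1 and 208 in replicate 2), which was removed, and the range of the values was then asserted. No row was 0 in both replicates, so genes without reads in both are not listed. The 104 rows that name part of a gene by coordinates and the 12 rows that share a name with another row were left out. A further 6 names had been turned into dates by a spreadsheet and were kept as unnamed genes. This left 19874 genes. Names were matched to release 115 of the WBcel235 annotation: 15965 by symbol, 2883 by sequence name and 1026 not at all. Of 92 coordinate rows whose gene has that name, 39 were as long as the annotated coding span with its stop codon, with starts counted from 0, and in all 39 both ends were moved by the same number of bp, from 1 to 100, so the table's positions belong to another build. Only chromosome, coding length and biotype were taken from WBcel235 for analysis, and positions printed in the report are those of WBcel235.

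Depth was estimated from the low values. RPKM times coding length came out as whole multiples of the value of 1 read, within 0.1 read, for 83.3% of 4987 values up to 20 reads in replicate 1 and 83.6% of 3810 in replicate 2, where 20% is given by chance. These steps correspond to about 10600000 and 14700000 reads. Read numbers in the report are such estimates. The floor is 3 reads, and intervals are exact Poisson intervals at a confidence level of 95% that cover counting error only.

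Both samples form 1 group, and their replicate numbers come from the labels. Tests between groups were not possible, and no p-value was calculated. Expression was set on the log2(RPKM + 1) scale, which understates differences of low genes. Replicates were compared by correlation across genes and by the log2 ratio of replicate 2 to replicate 1, for genes with a mean RPKM of at least 1 and a limit of 2-fold. The 52 gene lists (tissues, stages, pathways and families) were written before the data were examined. A list with at least 5 genes was placed as a percentile among 10000 random lists of the same size, drawn with replacement, and stood apart below 2.5 or above 97.5. For replicate differences the random lists were matched on mean expression in 20 bins. Class 1 and class 2 targets of DAF-16 were compared within the strain by the difference of their medians, against 10000 pairs of random lists.

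Named genes were fixed by rule: the members of the insulin signalling and steroid hormone lists, the 10 genes of highest mean RPKM, the 3 highest and the lowest member of each list, and the 10 largest and 10 lowest replicate ratios among genes with a mean RPKM of at least 5 and both values above 0. Other genes are named as chosen after their values were seen. Only some of the genes that the rule names have their values given in the report. Alternatives were other pseudocounts, RPKM limits, fold limits and filters, rescaling of each replicate to an equal sum, scaling to a median log2 ratio of 0, quantile normalization, and leaving out each replicate. Matching on coding length in 5 bins and a minimum of 100 reads were added after seeing the data.

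The scripts were tested on simulated data of 17891 genes with depths of 9000000 and 16000000 reads, which were recovered as 9001000 and 16000000 reads. For the replicate difference of gene lists, 20 of 20 lists of 20 genes shifted by 0.3 (log2) stood apart, as did 6 of 100 unshifted lists. These lists held only genes with a mean RPKM of at least 5. Smaller shifts, other list sizes and lower genes were not tested for this comparison. Simulated genes varied independently, so lists whose genes change together were not tested. All 200 genes changed by 2 on the log2 scale lay beyond 2-fold, with 43 unchanged genes. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.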

Results

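RNA sequencing was carried out on total RNA from mixed-stage cultures of the nematode Caenorhabditis elegans, so each value averages animals of different stages. The 2 samples were replicates 1 and 2 of 1 strain that carries daf-2(e1370), an allele of the insulin/IGF-like receptor gene, together with daf-12(m20), an allele of a nuclear hormone receptor gene of the dauer decision. The labels do not say whether the replicates came from separate cultures, so their spread may be technical. Expression was given by the authors as RPKM, read numbers scaled to gene length and library size. The steps between low RPKM values corresponded to depths of about 10600000 reads for replicate 1 and 14700000 reads for replicate 2. A floor of 3 reads in a gene with 1 kb of coding sequence was 0.283 RPKM in replicate 1 and 0.204 RPKM in replicate 2, and such limits cover counting error only. No wild type or single mutant was analysed here, so no value below shows a gene to be raised or lowered by the mutations.

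Both mutated genes were expressed. daf-2 was at 14.3 ± 0.41 RPKM (SD, n = 2), and daf-12 was at 13.4 ± 0.21 RPKM (SD, n = 2). For daf-2, about 894 reads in replicate 1 and 1193 reads in replicate 2 gave exact Poisson 95% intervals of 13.6 to 15.6 and 13.2 to 14.8 RPKM. For daf-12, about 327 and 465 reads gave intervals of 11.9 to 14.8 and 12.4 to 14.9 RPKM. The replicates thus did not differ beyond counting error in either gene. In the WBcel235 annotation daf-2 lies on chromosome III from 2994514 to 3040846, and daf-12 lies on chromosome X from 10635908 to 10666875. Levels of RPKM do not show whether a point mutation is present.

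Genes of the insulin signalling, steroid hormone and TGF-beta dauer lists were nearly all at a mean RPKM of at least 1. All 18 insulin signalling genes had a mean RPKM of at least 1, and their median of 34.5 RPKM was higher than that of 99.88% of 10000 random lists of the same size. daf-16, the FOXO transcription factor of the pathway, was at 35.7 ± 0.90 RPKM. The 14-3-3 genes par-5 and ftt-2 were the highest of the list, at 784 ± 28.8 and 549.6 ± 35.6 RPKM. The phosphatidylinositol 3-kinase gene age-1 was at 10.9 ± 0.11 RPKM and the kinase gene pdk-1 at 10.7 ± 0.44 RPKM. The lowest member was ist-1, at 4.98 ± 0.10 RPKM. Of the 12 steroid hormone and DAF-12 genes, 11 had a mean RPKM of at least 1, and their median of 7.74 RPKM lay at percentile 61.9 of random lists. Within that list emb-8 was at 95.2 ± 2.58 RPKM and daf-36, an oxygenase gene of dafachronic acid synthesis, at 21.1 ± 2.85 RPKM. daf-9, the cytochrome P450 gene of the same route, was low at 2.17 ± 0.45 RPKM, with about 35 reads in replicate 1 and 65 reads in replicate 2. hsd-1 was at 0.14 RPKM in replicate 1 and listed at 0 in replicate 2, both under the floor. The 7 TGF-beta dauer pathway genes had a median of 10.7 RPKM, at percentile 69.6, with daf-14 highest at 27.3 ± 1.85 RPKM and the ligand gene daf-7 lowest at 1.32 ± 0.30 RPKM. Of 37 insulin-like peptide genes, 26 had a mean RPKM of at least 1, beside 14313 of all 19874 genes. Their median of 2.94 RPKM lay at percentile 11.6, and the highest was ins-35 at 129.6 ± 23.4 RPKM.

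The strain lowers DAF-2 signalling, which is known to raise 1 set of genes through DAF-16 (class 1) and to lower another (class 2). Within this strain the class 1 genes were the more abundant. The median of 33 class 1 genes was 178 RPKM and that of 15 class 2 genes was 15.7 RPKM. The difference of their medians on the log2(RPKM + 1) scale was 3.59 in replicate 1 and 3.35 in replicate 2 (mean 3.47 ± 0.17, SD, n = 2). Of the class 1 genes, 22 had a mean RPKM of at least 100. They included mtl-1, a metallothionein gene, at 786 ± 56.7 RPKM, sod-3, a manganese superoxide dismutase gene, at 133.5 ± 8.49 RPKM and dod-3 at 170.3 ± 18.1 RPKM, all 3 chosen after their values were seen. By the fixed rule the highest class 1 genes were the small heat shock genes hsp-16.49 at 1785 ± 16.6 RPKM, hsp-16.48 at 1779.6 ± 18.4 RPKM and sip-1 at 1467 ± 63.6 RPKM, and the lowest was sod-5 at 0.88 ± 0.52 RPKM. The highest class 2 genes were the yolk protein genes vit-2 at 2602 ± 95.1 RPKM and vit-5 at 2449.6 ± 143 RPKM, followed by dod-19 at 186 ± 0.93 RPKM. The lowest was gcy-6, at 0.08 ± 0.03 RPKM. The difference calculated on the mean of the replicates, 3.42, was larger than that of 99.94% of 10000 pairs of random lists of the same sizes. It was 2.01 when members with a mean RPKM under 1 were left out, at percentile 99.3. Without a wild type, these percentiles cannot tell whether the mutations caused the difference. A high level was also common among the lists, since 31 of 51 stood above random lists.

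Over all 19874 genes analysed, 13875 were at 1 RPKM or more in both replicates, 1473 at 100 RPKM or more and 199 at 1000 RPKM or more. The 100 highest genes held 29.4% of all RPKM. The highest was C17F4.7 at 8119 ± 171 RPKM. It was followed by F54D7.7, now named rpl-41.2, at 7466 ± 55.5 RPKM, the elongation factor gene eef-1A.1 at 6527 ± 283 RPKM, the fatty acid and retinol binding protein gene far-2 at 5749 ± 184 RPKM and rps-25 at 5509 ± 172 RPKM. The neighbouring genes F15E11.14 and F15E11.1 were at 5354 ± 7.74 and 5320.05 ± 74.9 RPKM, and reads of such near-identical copies can be split between them. pat-10, a muscle troponin C gene, was at 4766 ± 263 RPKM, dct-16 at 4665 ± 261 RPKM and rps-8 at 4519 ± 264 RPKM.

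Genes of protein synthesis and energy metabolism were abundant as groups. Of 80 cytosolic ribosomal protein genes, 77 had a mean RPKM of at least 100, and together they held 17.8% of all RPKM in replicate 1 and 18.5% in replicate 2. Their median was 2255 RPKM, and the lowest was rpl-37, at 0.59 ± 0.14 RPKM. The 29 nuclear genes of oxidative phosphorylation had a median of 388 RPKM, with cyc-2.1, a cytochrome c gene, at 1586 ± 119.9 RPKM. Glycolysis genes had a median of 150.4 RPKM, led by gpd-3 at 1333 ± 61.4 RPKM, and 16 genes of the glyoxylate, trehalose and gluconeogenesis list had a median of 75.1 RPKM, led by pck-2 at 1589.6 ± 30.5 RPKM. The 18 fatty acid desaturase and elongase genes had a median of 128 RPKM, led by elo-6 at 1406 ± 40.8 RPKM. The medians were 49.9 RPKM for 70 mitochondrial ribosome genes, 99.0 RPKM for 35 translation factor genes, 153.7 RPKM for 33 proteasome genes, 253 RPKM for 46 lysosome genes and 23.7 RPKM for 25 autophagy genes. All of these lists lay above the middle 95% of random lists, but autophagy did not when genes with a mean RPKM under 1 were left out (percentile 91.8). No row of the table matched a gene of the mitochondrial genome list, so that list has no value.

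Chaperone and stress genes were also high. The 14 small heat shock genes had a median of 504 RPKM, and 10 of them were at a mean RPKM of at least 100. hsp-16.1 at 1451 ± 135 RPKM, hsp-16.41 at 902 ± 164 RPKM and hsp-16.2 at 750.5 ± 160.9 RPKM were chosen after their values were seen, as were the Hsp70-type genes F44E5.5 at 1399.6 ± 94.6 RPKM and F44E5.4 at 1392 ± 87.9 RPKM. Members of these groups are near-identical copies, so reads shared between them leave each single value uncertain. The lowest small heat shock gene was hsp-12.6, at 17.9 ± 0.08 RPKM. Among 19 chaperonin and heat shock genes the median was 162.5 RPKM, with the constitutive Hsp70 gene hsp-1 at 1233 ± 13.7 RPKM and the Hsp90 gene daf-21 at 1151 ± 26.5 RPKM. The unfolded protein response genes had a median of 117.5 RPKM, led by the calreticulin gene crt-1 at 1362 ± 26.5 RPKM. Of 18 antioxidant enzyme genes, 16 had a mean RPKM of at least 1, with prdx-2, a peroxiredoxin gene, at 1173 ± 21.2 RPKM and sod-1 at 505 ± 29.3 RPKM. These lists all lay above the middle 95% of random lists.

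**Figure D1:**
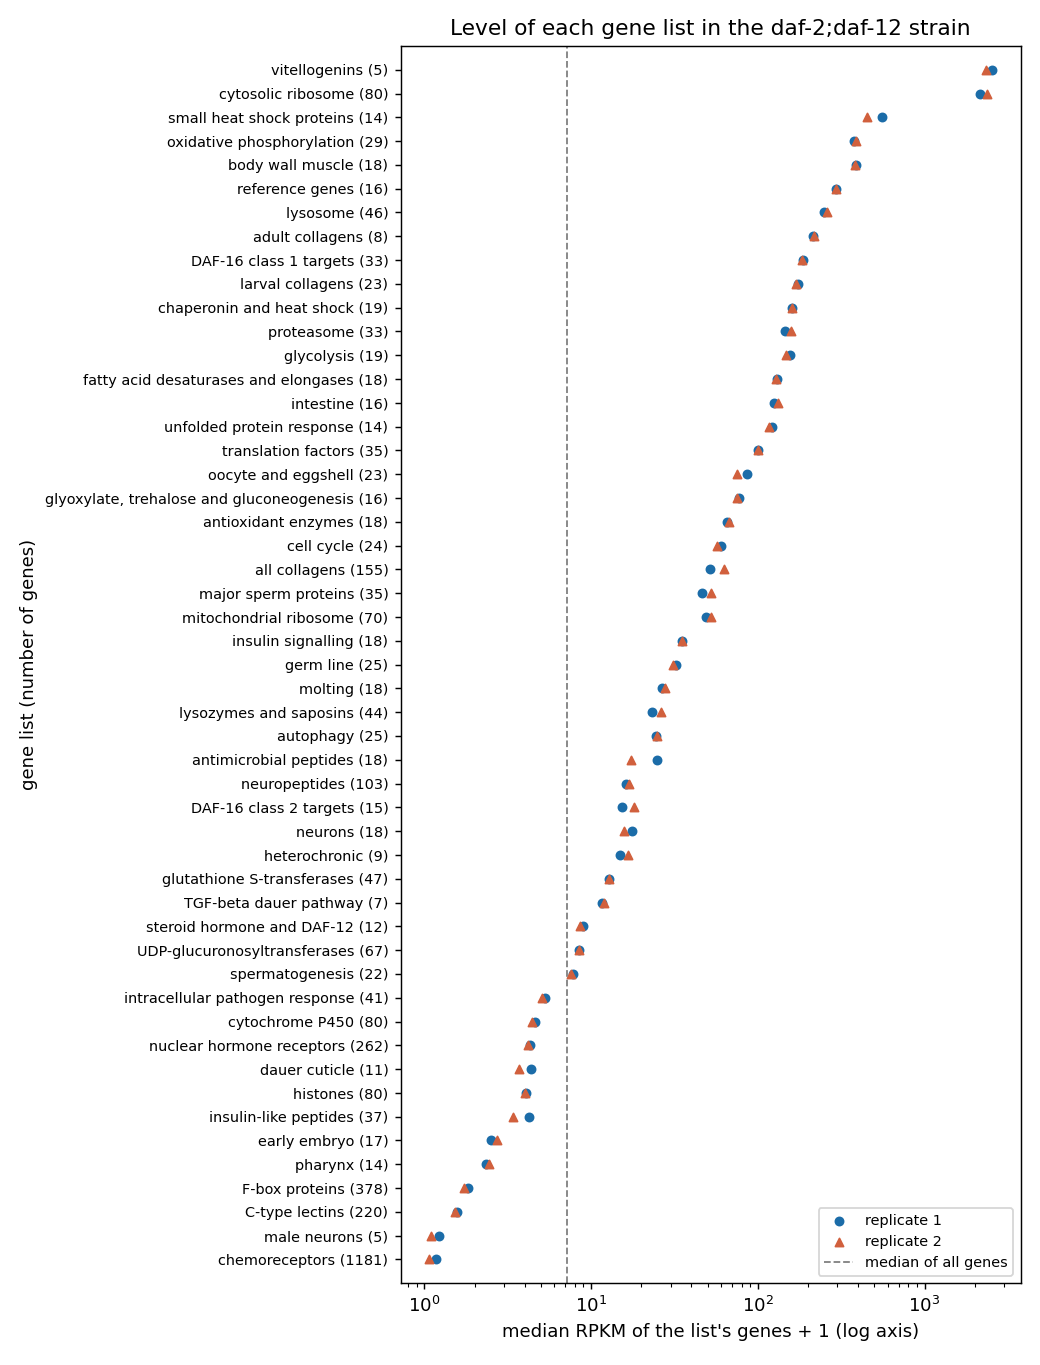
Median RPKM + 1 (log axis) of the genes in each list (number of genes in brackets), with a circle for replicate 1, a triangle for replicate 2 and a dashed line at the median of all 19874 genes. Vitellogenins and cytosolic ribosomal proteins stand above 2000 RPKM in both replicates, and chemoreceptors are lowest at 0.17 and 0.07 RPKM.

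Markers of adult reproduction, of the cuticle and molting, and of several tissues were present together. The 5 vitellogenin genes, which encode yolk proteins made by adult hermaphrodites, had a median of 2449.6 RPKM, with vit-6 at 3055 ± 139 RPKM and vit-1 lowest at 363 ± 41.4 RPKM. The 23 oocyte and eggshell genes had a median of 79.3 RPKM, led by perm-2 at 718 ± 28.7 RPKM and cpg-2 at 473 ± 19.3 RPKM, and 25 germ line genes had a median of 30.5 RPKM, led by cgh-1 at 286 ± 31.3 RPKM. The 35 major sperm protein genes had a median of 51.8 RPKM, with msp-19 at 178 ± 33.2 RPKM, while 22 other spermatogenesis genes had a median of 6.69 RPKM, at percentile 54.97, with ssq-4 highest at 65.65 ± 6.26 RPKM. Early embryo genes were lower, with 10 of 17 at a mean RPKM of at least 1 and end-1, an endoderm factor gene, at 0 and 0.10 RPKM. Adult collagen genes had a median of 216 RPKM, led by col-140 at 3911 ± 161 RPKM and col-19 at 3054 ± 192 RPKM. Larval collagen genes had a median of 177 RPKM, led by col-10 at 1542 ± 160.1 RPKM. That list holds cuticle collagens with body-shape phenotypes or larval expression, so its level does not by itself show larvae. All 155 col genes together held 7.22% of RPKM in replicate 1 and 7.17% in replicate 2. The 18 molting genes had a median of 26.2 RPKM and 24 cell cycle genes a median of 57.7 RPKM. The list named dauer cuticle holds 11 genes known from the dauer larva, not all of them cuticle genes. Their median was 3.24 RPKM (percentile 26.8), with cut-1 lowest at 0.09 ± 0.03 RPKM. The 9 heterochronic genes had a median of 14.7 RPKM, at percentile 82.97. Molting genes no longer stood above random lists when genes with a mean RPKM under 1 were left out (percentile 93.4).

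Among tissues, body wall muscle genes had a median of 385 RPKM and intestinal genes 127 RPKM, both above the middle 95% of random lists. Examples were the actin gene act-4 at 2929 ± 73.6 RPKM and the aspartyl protease gene asp-1 at 2538 ± 213 RPKM. The giant muscle gene ttn-1 was lowest of the muscle list, at 0.28 ± 0.07 RPKM. Neuronal genes had a median of 15.7 RPKM (percentile 92.2), with the synaptobrevin gene snb-1 at 164 ± 14.2 RPKM, and pharyngeal genes had a median of 1.42 RPKM (percentile 7.0), with the troponin I gene tni-4 at 28.2 RPKM in replicate 1 and 27.8 RPKM in replicate 2. The 103 neuropeptide genes had a median of 16.24 RPKM, led by nlp-24 at 640.1 ± 40.6 RPKM, and stood above random lists except when genes with a mean RPKM under 1 were left out (percentile 86.0). Male neuron genes were low: none of 5 reached a mean of 1 RPKM, and pkd-2 was at 0.40 RPKM in replicate 1 and 0.03 RPKM in replicate 2. The 16 reference genes had a median of 294 RPKM, led by act-2 at 2920.3 ± 179 RPKM.

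Large families of receptors and defence genes covered a wide range. Chemoreceptor genes were the lowest list: 84 of 1181 had a mean RPKM of at least 1, and the median was 0.105 RPKM. The 3 highest members of that list, C06A8.3, C42D4.1 and K01C8.1, were among 25 that entered it only through current symbols beginning with srlf or srdh, which are not receptor names. F-box genes had a median of 0.74 RPKM, C-type lectin genes 0.61 RPKM and nuclear hormone receptor genes 3.27 RPKM, all below the middle 95% of random lists. Single members were nevertheless high, such as clec-63 at 1200.3 ± 8.78 RPKM and nhr-68 at 177 ± 7.72 RPKM. C-type lectins did not stand apart when genes with a mean RPKM under 1 were left out (percentile 17.2). The detoxification lists lay within the middle 95% of random lists, with medians of 3.52 RPKM for 80 cytochrome P450 genes (percentile 8.81), 7.24 RPKM for 67 UDP-glucuronosyltransferase genes (percentile 67.3) and 11.8 RPKM for 47 glutathione S-transferase genes (percentile 93.6). Lysozyme and saposin genes had a median of 25.1 RPKM, with spp-5 at 4359 ± 24.2 RPKM. Antimicrobial peptide genes had a median of 22.7 RPKM (percentile 97.8), led by nlp-27 at 362 ± 13.04 RPKM, but lay at percentile 94.0 without replicate 1 and at 90.2 when genes with a mean RPKM under 1 were left out. The 41 intracellular pathogen response genes had a median of 4.39 RPKM (percentile 27.2), and 80 histone genes, many of them near-identical copies, had a median of 3.22 RPKM (percentile 5.64). Most genes of the histone list were marked, when it was written, as lacking poly(A) tails. How the libraries treated such transcripts was not examined, so the histone level is uncertain. When genes with a mean RPKM under 1 were left out, 8 lists that had not stood apart did so. Class 2 targets lay above random lists (percentile 99.15), and below them lay histones and pharynx (both at or under percentile 0.01), intracellular pathogen response (0.53), cytochrome P450 (0.945), insulin-like peptides (1.13), dauer cuticle (1.555) and early embryo genes (1.83).

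The replicates were compared gene by gene, as the only repeat measurement in the design. Across genes, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.994 and Spearman's rho was 0.983. Among 14313 genes with a mean RPKM of at least 1, the log2 ratio of replicate 2 to replicate 1 had an SD of 0.25 and a median of -0.02, and 102 genes lay beyond 2-fold. Of these, 34 were higher in replicate 2 and 68 in replicate 1. Most rested on few reads, since 72 had fewer than 100 reads over both replicates and 8 had 100 or more. The remaining 22 had no coding length, so their reads could not be estimated. Among genes with a mean RPKM of at least 5, the largest ratios toward replicate 1 belonged to the chemoreceptor genes srg-13, at 18.7 RPKM in replicate 1 and 1.22 RPKM in replicate 2, and srh-294, at 9.44 and 0.66 RPKM. bli-2, a cuticle collagen gene, was at 19.7 and 7.66 RPKM, and F35E12.5, now named irg-5, at 15.7 and 5.29 RPKM. The largest toward replicate 2 belonged to nspe-2, at 1.76 and 9.16 RPKM, and M117.6, at 3.51 and 13.5 RPKM, followed by nspd-11, K07C5.13 and the sperm gene msp-10, at 3.46 and 11.02 RPKM. C48E7.7 was the only gene beyond 2-fold with a mean RPKM of at least 100, at 71.7 and 156 RPKM. The replicates differed by more than sampling noise. For 738 genes with at least 5000 reads over both, the SD of the log2 ratio was 0.11 where sampling alone gives 0.03. In proportion to sampling noise the excess was smaller at low depth, though the gap itself was not. For genes with 20 to 50 reads the SD was 0.67 where sampling gives 0.54. This excess does not decide whether the replicates came from separate cultures.

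**Figure D2:**
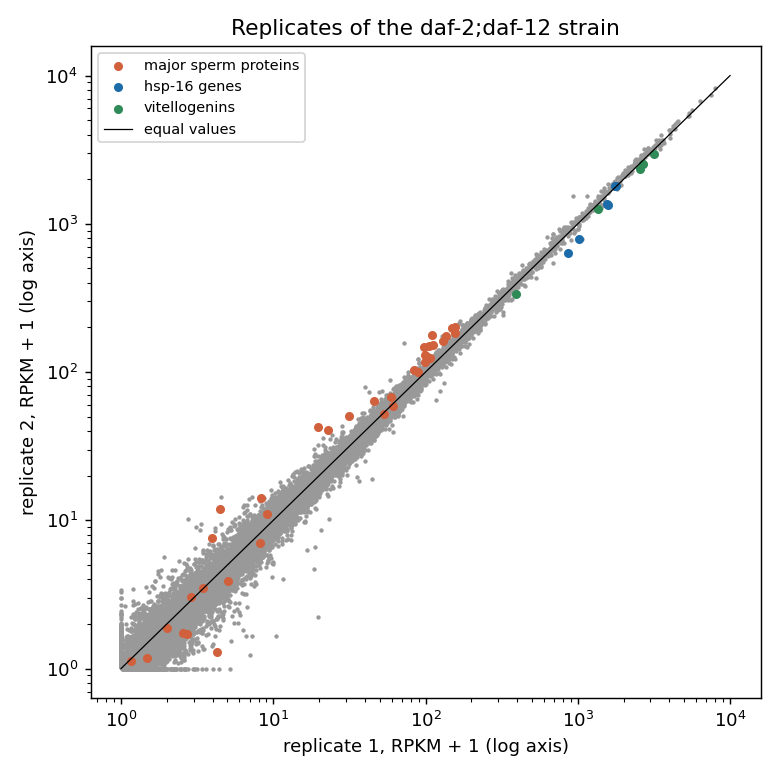
RPKM + 1 of each of the 19874 genes in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with major sperm protein, hsp-16 and vitellogenin genes in colour and a line at equal values. Points follow the line (Pearson's r 0.994 on the log2 scale) and most major sperm protein genes lie above it.

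The largest list medians between the replicates were those of antimicrobial peptide genes, toward replicate 1, and of major sperm protein genes, toward replicate 2. Major sperm protein genes had a median log2 ratio of replicate 2 to replicate 1 of 0.30, with 25 of 32 genes higher in replicate 2 and none of 10000 random lists matched on mean expression as high. The other spermatogenesis genes had a median of 0.02, within the middle 95% of random lists. All 25 germ line genes were lower in replicate 2 (median -0.11), as were 6 of 8 adult collagen genes (median -0.15) and 81 of 130 col genes (median -0.05). These 4 lists stood apart from random lists in the main comparison and in every alternative. A further 7 of the 50 lists stood apart but lost the call in at least 1 alternative. By chance 2.5 lists would be expected to stand apart if the genes of a list varied independently. Genes of 1 family can change together or share reads, and the adult collagen and col lists overlap, so more lists may stand apart by chance. The 79 cytosolic ribosomal protein genes had a median of 0.10, with 71 higher in replicate 2, but lay at percentile 89 after quantile normalization, as did glycolysis (median 0.08, then percentile 92.6) and oocyte and eggshell genes (median -0.07, then percentile 6.72). Vitellogenins were lower in replicate 2 in 5 of 5 genes (median -0.11) and histones had a median of 0.07, but with random lists matched also on coding length, chosen after seeing the data, they lay at percentiles 6.91 and 93.3. Oxidative phosphorylation genes had a median of 0.08, with percentile 96.3 among genes of at least 100 reads, which was likewise chosen after seeing the data. The antimicrobial peptide genes had a median of -0.31, which was -0.02 (percentile 43.7) for a mean RPKM of at least 5. With 1 library on each side, these percentiles describe the 2 libraries and no p-value was calculated.

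**Figure D3:**
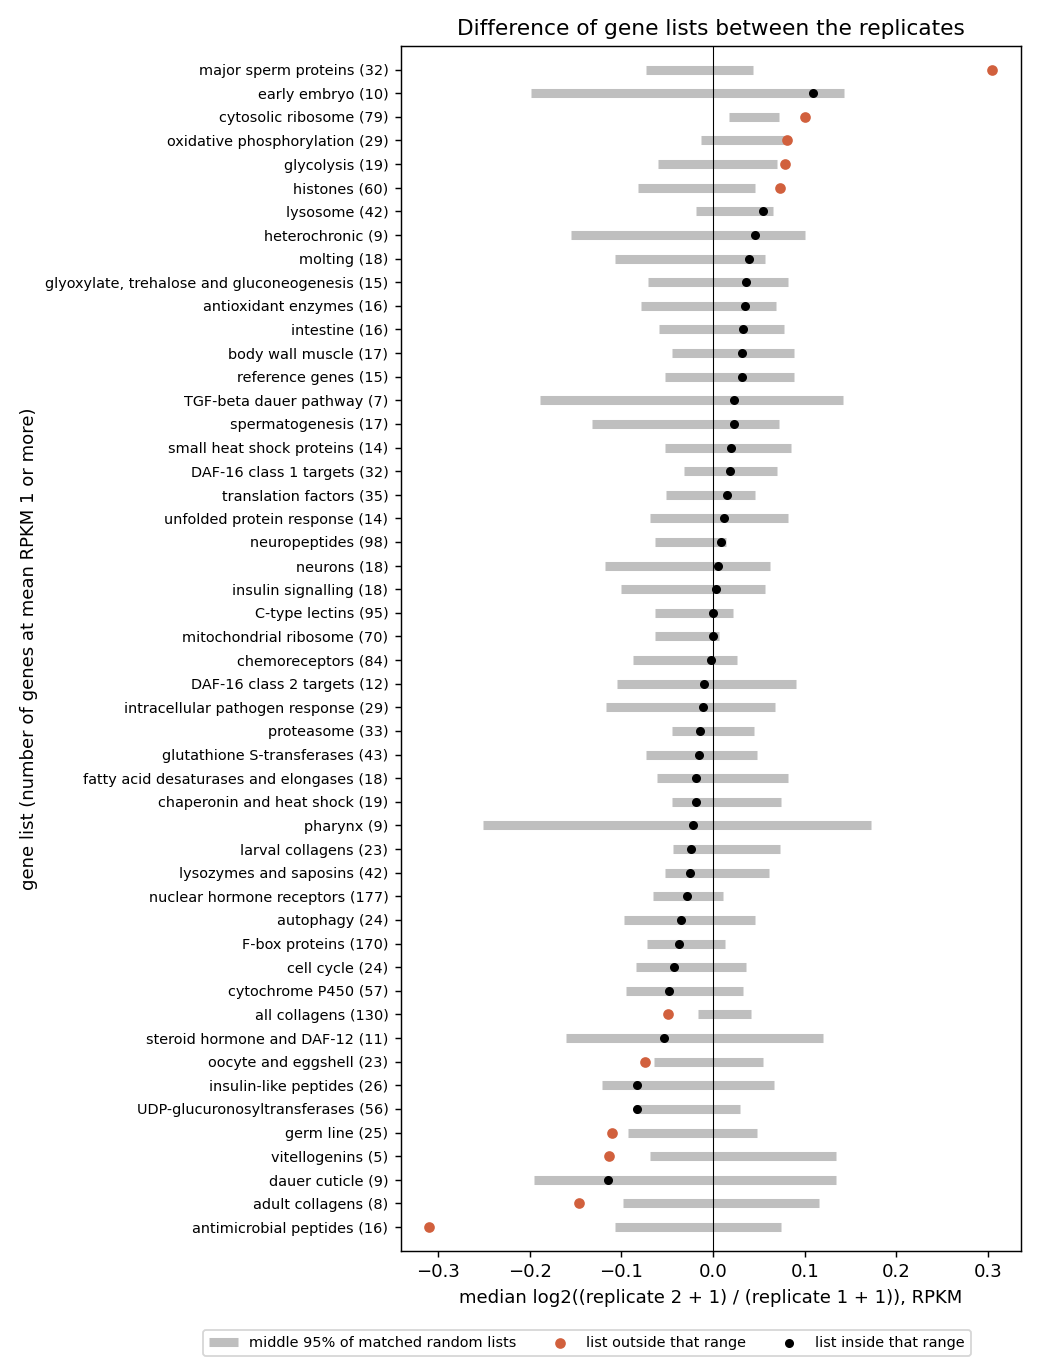
Median log2 ratio of replicate 2 to replicate 1, on the RPKM + 1 scale, for genes of each list with a mean RPKM of at least 1 (points), over the middle 95% of 10000 random lists matched on mean expression (grey bars). Major sperm protein genes lie highest at 0.30 and antimicrobial peptide genes lowest at -0.31, and coloured points mark lists outside the bars.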

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

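The minimum of 100 reads and the matching on coding length were chosen after seeing the data, and the other settings before the data were examined. The count of genes beyond 2-fold between replicates, 102, depended strongly on the pseudocount, the filters and the fold limit. It was 297 with a pseudocount of 0.1, 176 with 0.5 and 10 with 5. It was 155 with no filter on low values, 21 at a mean RPKM of at least 5 and 512 with a 1.5-fold limit. For genes with at least 100 reads it was 8, which leaves out genes without a coding length. Pearson's r across genes was 0.977, 0.991 and 0.997 with pseudocounts of 0.1, 0.5 and 5, 0.992 for genes with a mean RPKM of at least 1 and 0.996 for at least 100 reads. Lists with a level below random lists numbered 10 in place of 5 when genes with a mean RPKM under 1 left both members and background. Of 31 lists above random lists in level, 27 kept the call in every alternative, and 8 of 15 without a call gained one in some alternative. Of 5 lists below, 4 kept the call in every alternative that gave a value. One of these 4, male neurons, has no value when genes with a mean RPKM under 1 are left out, because none of its genes reached that level, so its call was not tested there. Other pseudocounts, rescaling to an equal sum and quantile normalization scarcely reorder genes, and with them none of the 51 level calls changed. The level calls were therefore tested mainly by the RPKM filter and by leaving out a replicate. Of 11 lists whose replicate difference stood apart, 4 kept the call in every alternative. Of 39 lists without such a call, 6 gained one in some alternative: molting, fatty acid desaturases and elongases, UDP-glucuronosyltransferases and neuropeptides on the side they already lay on, and 2 on the opposite side, insulin-like peptides with a median log2 ratio of 0.13 for a mean RPKM of at least 5 and chemoreceptors with -0.12 with no filter. Without the filter the chemoreceptor list takes in 1035 genes under 0.5 RPKM. These averaged 0.166 RPKM in replicate 1 and 0.078 RPKM in replicate 2, part of the low-level excess treated below. What caused that excess stayed open, and the cause of the insulin-like peptide change was not tested. Rescaling each replicate to an equal sum, which multiplies the values by 0.959 and 0.940, gave 13.6 RPKM for daf-2 and 12.7 RPKM for daf-12. The difference of class 1 and class 2 targets stayed above the middle 95% of random pairs in all 8 alternatives, from 2.01 to 4.42, and from 3.35 to 3.59 when either replicate was left out. No paired analysis was possible because the design has 1 group.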

Other observations

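The tests below were chosen after the values they rest on, or closely related values, were seen, except the comparison of low-level excess between gene classes.

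Expression differed between chromosomes. Protein-coding genes of chromosomes I and III had median RPKM of 13.5 and 14.6, those of V and X 3.12 and 5.76, and those of II and IV 6.94 and 9.37. The share of genes at a mean RPKM of at least 1 was 86.4% on III and 63.2% on V. A cluster of pud genes on chromosome V, chosen after its values were seen, held some of the most abundant transcripts. F15E11.13 was at 2938 ± 49.8 RPKM, F15E11.15 at 1172 ± 18.5 RPKM and F15E11.12 at 670.4 ± 48.7 RPKM (SD, n = 2), beside F15E11.14 and F15E11.1 named in the report. The lipid binding genes far-1 at 2987 ± 174 RPKM and far-3 at 925 ± 194 RPKM, also chosen after their values were seen, were high as well.

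Heat shock genes were among the most abundant transcripts although the labels give a culture temperature of 20 °C and name no heat treatment. The 8 genes (hsp-16.1, hsp-16.11, hsp-16.2, hsp-16.41, hsp-16.48, hsp-16.49, F44E5.4 and F44E5.5) summed to 11460.1 RPKM in replicate 1 and 10363 RPKM in replicate 2. Reads counted once for each of 2 near-identical copies do not account for this level: with its RPKM divided by 2, the lowest of the 8 genes still lay at percentile 97.7 of all genes. Exposure to heat or another stress before harvest and lowered insulin signalling in the strain, the explanation the design names, both remain open without a control culture. The stress gene hsp-70, known to be barely transcribed without stress and chosen after its values were seen, was at 89.2 RPKM in replicate 1 and 78.8 RPKM in replicate 2 (mean 84.0), which fits stress but does not show it. The 24 class 1 genes without small heat shock genes lay at percentile 100 of random lists, but 31 of 51 lists stood above random lists, so this level decides nothing.

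Major sperm protein genes were higher in replicate 2, where their summed RPKM was 2541 against 1946 in replicate 1. A different division of reads among near-identical copies leaves the sum of the family unchanged, but the sum rose by 0.39 on the log2 scale, more than 2 SDs (0.11) of genes with at least 5000 reads. Short coding length was also argued against, as the list lay at percentile 100 with random lists matched on length. More sperm in replicate 2 may account for the pattern but cannot be told apart here from a change in these genes alone: the other spermatogenesis genes had a median log2 ratio of 0.022, with members on both sides. The design names a possible biological source, that mixed-stage cultures can differ in stage, and it was not tested here.

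More genes had a few reads in replicate 1 than in replicate 2, with 718 genes at 0 in replicate 1 and 1201 in replicate 2. Depth argues the other way, since replicate 1 had 0.720 times the depth of replicate 2. A floor on low read numbers in replicate 2 would remove genes with 1 read, but these were 1.75 times as many as genes with 2 reads. Background spread evenly over all genes would raise every class alike, but among genes under 0.5 RPKM the excess of replicate 1 was 0.0882 RPKM in chemoreceptors and 0.0305 RPKM in pseudogenes, a ratio of 2.89, with 95% bootstrap intervals that did not overlap. An uneven background, or another difference between the 2 samples, may remain, and no biological explanation was tested.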
